A study of Mus musculus with 6 samples.

How the data were processed

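RNA was sequenced from 6 samples of mouse bone marrow-derived macrophages, 3 XWT and 3 XKO, grouped by their titles and source names. Per the labels' protocols, RNA was taken with Trizol after 48 h in hepatocyte-conditioned medium and libraries were made with the NEBNext Ultra RNA library kit. The submitters' processing notes name Bowtie 0.12.2 and the genome builds mm8 and mm10, with no role or order. The counting program, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Of the 54532 genes in the table, 54409 had an ID in GENCODE M21 (GRCm38) and 98.3% of these had the same coordinates, and coordinates are printed as the table gives them.

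The authors deposited 1 table for the whole series. Its count columns hold whole numbers of reads per Ensembl gene, per the file headers, with no scaling. Its FPKM columns hold values per kilobase and per library total, deposited by the authors with a scaling between libraries, since the totals they imply lie at 0.998 to 1.01 times the TMM-scaled library sizes; they were not used in a test. The authors also deposited scaled group means, treated as a signal, a log2 fold change of XKO over XWT, a p-value and an adjusted p-value, per the file headers. The tool behind these columns is not given in the sources used here, but DESeq2 run on the counts gave the same 882 higher and 1229 lower genes. Of the genes, 23413 have a log2 fold change in the authors' deposited table, and 7263 of them an adjusted p of 1.

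Tests were run on the counts with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (14333 of 54532; 29101 had no count in any library), libraries were scaled by TMM, and a robust quasi-likelihood fit compared XKO with XWT with 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM are TMM-scaled. The TMM factors were 0.951, 0.967 and 1.012 for XWT 1 to 3, and 1.03, 1.027 and 1.015 for XKO 1 to 3. At these depths of 28354866 to 30891729 counts, the biological coefficient of variation was 0.0865, and for genes with few counts counting error adds to this spread.

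Before the data were examined, 29 gene lists, the tests, most alternatives and the rule for named genes were fixed. The rule names Xbp1 and Lyz2 always. It then takes the 12 largest rises and 12 largest falls among genes with an adjusted p under 0.05, groups that do not overlap, a mean of at least 5 CPM in the higher group and a symbol of no predicted gene or pseudogene. From each list it takes up to 4 called members with the smallest p, or 2 where none is called. Some genes that the rule names are not reported here. Lists of at least 5 tested members (24 of 29) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, against all other tested genes, with adjustment over the 24 lists. With the correlation estimated from the residuals, camera called 0 of the 24 lists against 13 with the preset value. The lists cover XBP1 and ER genes, the PERK and ATF4 response, IRE1-cleaved RNA, inflammasome, cytokines, interferon, cGAS-STING, autophagy, alternative activation, profibrotic genes, metabolism, MHC class II, lysosome, NRF2, cell cycle, macrophage identity and markers of other cell types.

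The scripts were tested on simulated counts drawn from these libraries' means and sizes for XKO against XWT (14094 genes run). Of 50 genes changed at each size, 22% were recovered at 1.25-fold, 76% at 1.5-fold, 90% at 2-fold and 100% at 4-fold, with 8 false calls. The simulation gave both groups the same dispersion of a gene, as the test assumes, whereas the real XWT libraries varied more than the XKO libraries. These shares and false calls hold for that setting and are no error rates for the real data. With no list shifted 0 of 24 lists were called, and with 1 list shifted 1 was called. The simulated genes were drawn independently of each other. The list result therefore holds for uncorrelated genes only and cannot decide between the preset and the estimated correlation.

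Alternatives were other scaling factors, no filter and a stricter one, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, other thresholds, only established symbols, camera with an estimated correlation, fry, and lists without shared members. Added after the data were seen were quality weights per library, removal of length and GC trends, the authors' deposited table, and a count without genes over 4-fold lower. GC content and length were known for 99.9% of the tested genes.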

Results

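Messenger RNA levels were measured by RNA sequencing in mouse bone marrow-derived macrophages (BMDMs), macrophages grown in culture from bone marrow precursors. The animals were C57BL/6 mice of 32 to 34 weeks. One group, XWT, carried Xbp1 alleles flanked by recombination sites, and the other, XKO, lacked Xbp1 in macrophages by its label. Xbp1 encodes a transcription factor of the unfolded protein response that is activated when the endoplasmic reticulum (ER) sensor IRE1 splices its RNA. Both groups were primed with lipopolysaccharide and then kept for 48 h in medium conditioned by primary hepatocytes of wild-type mice. The series is about XBP1 in steatohepatitis, and its single comparison asks how loss of Xbp1 changes the transcripts of macrophages exposed to hepatocyte products. Each group had 3 libraries. The total counts were 28354866, 30707075 and 30891729 for XWT 1 to 3, and 30144453, 29965384 and 30184033 for XKO 1 to 3. The labels do not say whether the 3 samples of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

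Xbp1 was lower in all 3 XKO libraries. The gene (ENSMUSG00000020484, protein-coding, chromosome 11 from 5520659 to 5525893, plus strand) stood at 149 ± 15.0 CPM (SD, n = 3; CPM, counts scaled to a common library total) in XWT and 77.6 ± 1.58 CPM (SD, n = 3) in XKO. The log2 fold change was -0.94 with a standard error of 0.077, a 1.92-fold lower level (edgeR quasi-likelihood test, adjusted p = 1.93e-06). The count covers the whole gene and includes reads outside any deleted part, so it is only a partial check of the genotype labels. Lyz2 (ENSMUSG00000069516, chromosome 10 from 117277331 to 117282321, minus strand), the main lysozyme gene of macrophages, fell from 31140 ± 3553 to 14274 ± 583 CPM (SD, n = 3 each). Its log2 fold change was -1.13 with a standard error of 0.086 (edgeR adjusted p = 1.06e-06). Its neighbouring near-identical paralog Lyz1 rose from 8.58 ± 1.47 to 17.9 ± 0.10 CPM (SD, n = 3 each), and because reads can be shared between such copies the Lyz1 value is uncertain. The authors' deposited table gives log2 fold changes of -0.95 for Xbp1 and -1.13 for Lyz2.

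**Figure D1:**
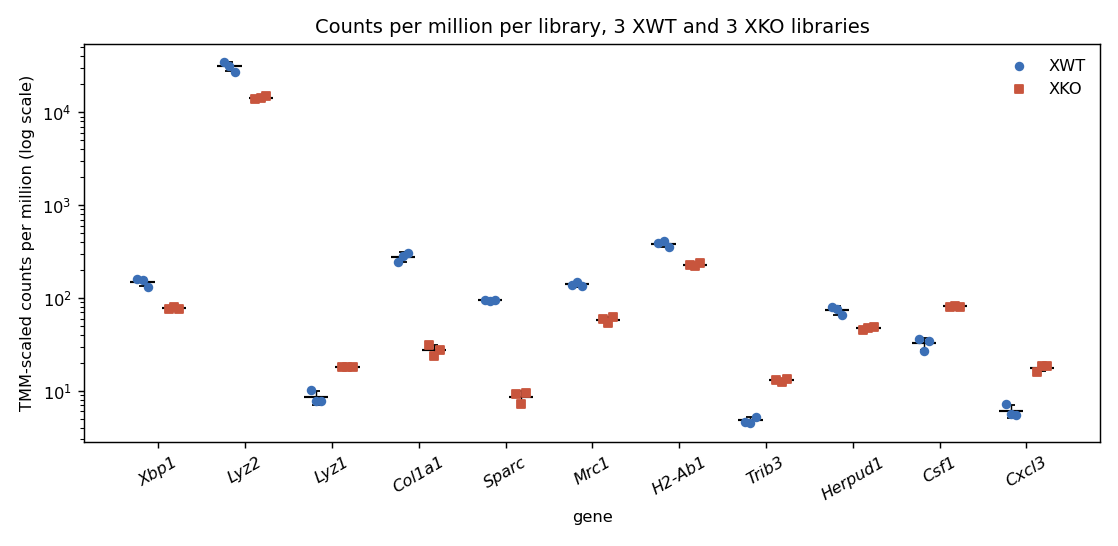
TMM-scaled CPM on a log axis for 11 genes in the 3 XWT (circles) and 3 XKO (squares) libraries, with the group mean as a line and the SD as the error bar. Xbp1 lies at 132 to 159 CPM in XWT and 76.6 to 79.4 CPM in XKO, and Sparc at 93.8 to 96.0 CPM in XWT and 7.15 to 9.50 CPM in XKO.

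The largest falls were larger than the largest rises, while the median log2 fold change of the called genes was -0.47 for falls and 0.42 for rises. Among genes of at least 5 CPM in the higher group with established symbols, the strongest falls were in genes related to the extracellular matrix or to contractile cells. They were the smooth muscle actin gene Actg2 (log2 fold change -4.63), the myosin light chain gene Myl9 (-4.32) and the collagen genes Col6a1 (-4.01), Col3a1 (-3.87) and Col6a2 (-3.65). They also included the matrix-related genes Pxdn (-3.95), Loxl1 (-3.79), Fkbp10 (-3.79), Bgn (-3.73), Cemip (-3.72), Fbln2 (-3.71) and Cyr61 (-3.67). The strongest rises within the same limits were Dio2 (1.55), a deiodinase that activates thyroid hormone, the neutrophil-attracting chemokine genes Cxcl3 (1.55) and Cxcl2 (1.15), the stress-response pseudokinase gene Trib3 (1.43), the macrophage growth factor gene Csf1 (1.32), the cystine transporter gene Slc7a11 (1.27), and Slfn4 (1.28), Cd24a (2.38-fold), Cd300lf (1.11), Ndrg4 (1.09), Lyz1 (1.07) and Ly6c2 (1.07). Standard errors of these rises lay between 0.096 and 0.205 and those of the falls between 0.108 and 0.282. Of 14333 genes tested, 860 were higher and 1145 lower in XKO at an adjusted p under 0.05 (edgeR quasi-likelihood test). Among these, 109 were at least 2-fold higher and 372 at least 2-fold lower, and 10 were at least 4-fold higher and 250 at least 4-fold lower. The values of the 2 groups did not overlap for 1998 of the 2005 changed genes, and for 36.2% of all tested genes against 10% by chance. Scaling by library size alone gave 1158 higher and 749 lower genes (60.7% higher against 42.9%), and removing trends with gene length and GC content gave 1434 higher and 1042 lower (57.9% higher). The authors' deposited table has 882 higher and 1229 lower genes at the same threshold, of which 1860 were also called here, all in the same direction. DESeq2 run on the counts gave the same 882, 1229 and 1860, so the deposited table is no independent check beside DESeq2. The count changed with the libraries used. It was 4237 without XWT 3, 1209 without XWT 2, 915 without XKO 1, 806 without XKO 2 and 898 without XKO 3.

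**Figure D2:**
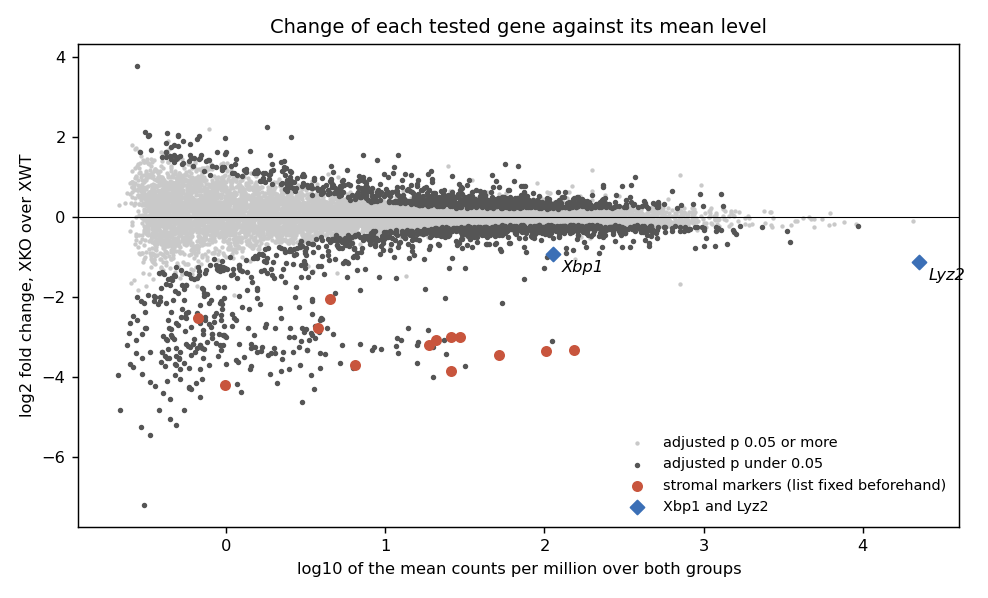
Log2 fold change of XKO over XWT (vertical axis) against the log10 of the mean CPM over both groups (horizontal axis) for the 14333 tested genes, with the 2005 changed genes in dark grey, the 13 tested stromal markers in red, and Xbp1 and Lyz2 as blue diamonds. The stromal markers lie together at a median of -3.22, well below Xbp1 at -0.94 and Lyz2 at -1.13.

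The libraries did not vary equally. A chi-square over genes gave 2.94 to 4.95 per gene between pairs of XKO libraries and 21.3 to 25.8 between pairs of XWT libraries, so that every pair differed by more than sampling noise. The edgeR fit took the same dispersion of a gene for both groups. Leaving out an XKO library removes a member of the tighter group and lowers the residual degrees of freedom. Calls lost without an XKO library, above and below, may therefore reflect lost power rather than dependence on that library. On the first principal component, with 61.4% of the variance, XWT 1, XWT 2 and XWT 3 stood at -36.9, -38.6 and -18.2, and the XKO libraries between 29.2 and 33.8. Genes of ribosomal RNA took 0.131%, 0.0777% and 0.110% of the counts in XWT 1 to 3, and 0.0232%, 0.0196% and 0.0621% in XKO 1 to 3. The 10 most abundant genes took 10.04% to 11.64% of the counts in XWT and 8.796% to 9.013% in XKO, in a comparison where Lyz2 itself fell.

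Markers of fibroblasts and stroma fell as a group, all 13 tested members being lower in XKO. Their median log2 fold change was -3.22 (camera with a preset correlation, adjusted p = 1.72e-21; adjusted p = 0.0539 with an estimated correlation), and 0 were higher and 13 lower when adjusted over the list alone. Sparc, a matrix glycoprotein, fell from 94.8 ± 1.09 to 8.62 ± 1.28 CPM (SD, n = 3 each). Col1a2, a chain of type I collagen, fell from 188 ± 16.7 to 18.2 ± 2.39 CPM, Col3a1 from 48.3 ± 5.46 to 3.31 ± 0.60 CPM, and the smooth muscle actin gene Acta2 from 52.4 ± 4.19 to 6.56 ± 0.85 CPM (SD, n = 3 each). All 13 were called without any 1 of the 6 libraries.

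Genes of ER protein folding, transport and degradation, many of them known XBP1 targets, were lower in part. Of 55 tested members 13 fell and 0 rose (0 higher and 14 lower adjusted over the list alone), with a list median of -0.11 (-0.04 with library size alone). The called members with the smallest p were Herpud1, which takes part in ER-associated degradation (-0.65 ± 0.081, SE), the translocon-associated Serp1 (-0.52 ± 0.077), the disulfide isomerase gene Pdia5 (-1.27 ± 0.209) and the ER co-chaperone gene Dnajb9 (-0.50 ± 0.092). The list was called by camera (adjusted p = 0.000446; adjusted p = 0.497 with an estimated correlation). The stromal markers, with a median log2 fold change of -3.22, fell between the same groups, and a link between the 2 lists was not tested. The 13 became 6 without XKO 1, XKO 2 or XKO 3, each left out in turn, and 20 without XWT 3.

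Genes of the PERK and ATF4 stress response changed both ways, more often upward, with 12 members higher, 4 lower and 14 not called of 30 tested. Adjusted over the list alone, 12 were higher and 4 lower, and the list median was 0.14. Trib3 rose from 4.80 ± 0.39 to 13.0 ± 0.45 CPM, Slc7a11 from 40.3 ± 7.58 to 97.1 ± 2.47 CPM and the transcription factor gene Ddit3, also called CHOP, from 17.9 ± 0.30 to 28.5 ± 1.01 CPM (SD, n = 3 each), and the stress cytokine gene Gdf15 rose by 0.72 on the log2 scale. The list was called by camera (adjusted p = 0.00207; adjusted p = 0.452 with an estimated correlation). The 12 became 5 without XKO 1, XKO 2 or XKO 3, and the 4 became 2 without XWT 2, XKO 1 or XKO 3. Transcripts reported in other cells to be cleaved by IRE1 were lower in 8 of 13 tested members and higher in 0 (0 higher and 10 lower adjusted over the list alone; median -0.32; camera adjusted p = 3.86e-07; adjusted p = 0.123 with an estimated correlation). Of these, Col6a1 (-4.01), Sparc (-3.46) and Pdgfrb (-2.06) are genes of matrix and mesenchymal cells, Sparc and Pdgfrb are also among the stromal markers, which had a median of -3.22, and the lysosomal enzyme gene Hgsnat fell by 0.91 on the log2 scale.

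Inflammatory cytokine genes and targets of NF-kB were mostly higher where they changed, with 13 members higher and 1 lower of 36 tested (16 higher and 3 lower adjusted over the list alone; median 0.13, and 0.19 without XKO 2). Csf1 rose from 32.5 ± 4.95 to 81.2 ± 1.71 CPM, Cxcl3 from 6.10 ± 0.99 to 17.8 ± 1.43 CPM and Cxcl2 from 12.1 ± 2.43 to 26.8 ± 1.75 CPM (SD, n = 3 each), and Tnf rose by 0.74 on the log2 scale. The list was called by camera (adjusted p = 0.00186; adjusted p = 0.497 with an estimated correlation). The 1 lower gene became 0 without XWT 1, XKO 1, XKO 2 or XKO 3 and 4 without XWT 3. Of 17 tested inflammasome genes, 5 were higher and 2 lower (5 and 2 adjusted over the list alone), and the list did not pass the test (median 0.13; camera adjusted p = 0.0586). Il1a rose by 1.18, the DNA sensor gene Aim2 by 0.39 and the sensor gene Nlrp3 by 0.39 on the log2 scale, and Txnip fell by 0.66. The 5 became 3 without XKO 1 or XKO 2 and 2 without XKO 3, the 2 became 1 without any XKO library, and the call of Aim2 ended without XKO 3. The inflammasome list was called higher without XWT 1 (camera adjusted p = 0.0389) and without XKO 2 (0.0415).

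Interferon-stimulated genes were higher in 12 of 50 tested members and lower in 1 (22 higher and 2 lower adjusted over the list alone; median 0.17). The antiviral gene Rsad2 rose from 69.4 ± 2.46 to 90.8 ± 5.03 CPM and the guanylate-binding protein gene Gbp7 from 18.8 ± 2.38 to 25.5 ± 1.82 CPM, and Ifi27l2a fell from 215 ± 37.0 to 139 ± 10.7 CPM (SD, n = 3 each). Herc6 rose by 0.62 on the log2 scale. The list was called by camera (adjusted p = 0.000117; adjusted p = 0.497 with an estimated correlation), and several of its members belong to families of near-identical genes, so single values are uncertain. The 12 became 5 without XKO 1 or XKO 2 and 2 without XKO 3, the 1 became 2 without XWT 1, and the call of Gbp7 ended without XKO 3. In the cGAS-STING pathway 4 members were higher and 3 lower of 15 tested (4 and 5 adjusted over the list alone; median 0.01; camera adjusted p = 0.969). The gene of cGAS, listed as Mb21d1, rose by 0.43 and the kinase gene Tbk1 by 0.26, while Ticam1 fell by 0.37 and Trim32 by 0.26 on the log2 scale. The 4 became 1 without XWT 2 or any XKO library and 2 without XWT 1; the 3 became 0 without XWT 2, XKO 2 or XKO 3, 1 without XWT 1 or XKO 1, and 5 without XWT 3. The calls of Tbk1 and Trim32 ended without each library but XWT 3, and that of Ticam1 without XWT 2, XKO 2 or XKO 3. With length and GC trends removed Ticam1 and Trim32 were not called, and Trim32 also not with DESeq2, library size alone, no filter or quality weights.

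Markers of neutrophils and granulocyte precursors rose, with 7 members higher and 0 lower of 10 tested (7 and 0 adjusted over the list alone; median 0.89). They are genes of granule and secreted proteins: Ltf rose from 0.96 ± 0.20 to 2.79 ± 0.17 CPM, Lcn2 from 13.4 ± 3.07 to 25.7 ± 2.43 CPM, Mmp8 from 11.7 ± 1.81 to 20.1 ± 1.03 CPM and S100a8 from 3.73 ± 0.47 to 6.97 ± 0.82 CPM (SD, n = 3 each). The list was called by camera (adjusted p = 2.28e-05; adjusted p = 0.0973 with an estimated correlation). These markers moved in the same libraries as the inflammatory and interferon lists described above, and a link between them was not tested.

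Genes of macrophage identity were lower in 5 and higher in 2 of 22 tested members (2 higher and 9 lower adjusted over the list alone; median -0.17). Besides Lyz2, the complement genes C1qb (1742 ± 189 to 1078 ± 52.2 CPM) and C1qc (1257 ± 177 to 764 ± 37.3 CPM; SD, n = 3 each) fell, and the 2 that rose were Lyz1 and the monocyte antigen gene Ly6c2, whose near-identical paralog makes its value uncertain. Camera called the list (adjusted p = 0.0422; adjusted p = 0.647 with an estimated correlation), but not without XWT 1 (median -0.09), XKO 1 (-0.16) or XKO 2 (-0.16) nor with length and GC trends removed (-0.11) or only members of a single list, and the 5 became 13 without XWT 3. Genes of antigen presentation by MHC class II and costimulation fell in 8 of 15 tested members and rose in 2 (2 higher and 8 lower adjusted over the list alone; median -0.39, and -0.69 with only members of a single list). H2-Ab1 fell from 383 ± 24.8 to 229 ± 7.79 CPM, the invariant chain gene Cd74 from 1120 ± 108 to 647 ± 29.3 CPM, H2-Eb1 from 227 ± 21.7 to 135 ± 4.54 CPM and H2-Aa from 287 ± 25.3 to 170 ± 9.29 CPM (SD, n = 3 each). By camera the list was called (adjusted p = 0.00383; adjusted p = 0.452 with an estimated correlation). The members that rose were the costimulatory gene Cd86 (0.69) and Cd274 (0.61), which encodes an inhibitory ligand, both named after their values were seen. Between the same groups the neutrophil markers rose (median 0.89) and the stromal markers fell (median -3.22). Whether these changes are linked to those of the MHC class II genes was not tested.

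Among genes of alternative activation, 3 were higher and 4 lower of 20 tested (4 and 6 adjusted over the list alone; median 0.04; camera adjusted p = 0.919). The mannose receptor gene Mrc1 fell from 140 ± 7.48 to 58.1 ± 4.35 CPM and the folate receptor gene Folr2 from 35.9 ± 4.08 to 14.7 ± 0.73 CPM, whereas Chil3 rose from 1.53 ± 0.13 to 3.18 ± 0.064 CPM and Egr2 from 16.1 ± 0.99 to 22.4 ± 1.35 CPM (SD, n = 3 each). The 4 became 2 without XKO 1 or XKO 2. Of 30 tested profibrotic and lipid-associated macrophage genes, 9 were higher and 11 lower (9 and 12 adjusted over the list alone; median -0.03; camera adjusted p = 0.111). The falls were led by Fn1 (-3.10), Ctgf (-3.42), Thbs1 (-2.15) and Timp1 (-2.92), all genes of matrix or matrix-associated proteins, and the stromal markers fell between the same groups (median -3.22). The profibrotic list was called lower with DESeq2 (camera adjusted p = 3.88e-08), quality weights (0.0341) and only members of a single list (0.0224). The 9 became 5 without XKO 1. Of 32 tested genes of lysosome and phagocytosis, 2 were higher and 5 lower (3 and 5 adjusted over the list alone; median -0.06; camera adjusted p = 0.477). Ctsk and Atp6v0d2, both also known from osteoclasts, rose by 0.55 and 0.68, while Lgmn fell by 0.52 and Fcgr3 by 0.45 on the log2 scale. The 5 became 2 without any library but XWT 3, and 13 without XWT 3, where the list was also called (median -0.11).

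Cholesterol synthesis genes were higher in 8 and lower in 0 of 24 tested members (10 and 0 adjusted over the list alone; median 0.11). Hsd17b7 rose from 18.1 ± 0.88 to 24.3 ± 1.13 CPM and Hmgcs1, the HMG-CoA synthase gene, from 73.7 ± 2.61 to 89.2 ± 4.84 CPM (SD, n = 3 each). Camera called the list (adjusted p = 0.00675; adjusted p = 0.452 with an estimated correlation), but not without XWT 3, where the median was 0.06 and 4 members were lower; without XWT 1 it was 0.18. The 8 became 4 without XKO 1 and 3 without XKO 2 or XKO 3, and the call of Hmgcs1 ended without XKO 2 or XKO 3 and with length and GC trends removed. Genes of oxidative stress and NRF2 were higher in 9 and lower in 0 of 25 tested members (10 and 2 adjusted over the list alone; median 0.14): besides Slc7a11, Gsr rose by 0.44, Nqo1 by 0.66 and Sod2 by 0.36 on the log2 scale. By camera the list was called (adjusted p = 0.00935; adjusted p = 0.618 with an estimated correlation), but not without XWT 3, where the median was 0.04 and 4 members were lower, and the 9 became 5 without XKO 2.

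Of 30 tested genes of glycolysis and hypoxia, 9 were higher and 2 lower (9 and 2 adjusted over the list alone; median 0.10; camera adjusted p = 0.0952), among them Vegfa (0.66), the glucose transporter gene Slc2a1 (0.34) and Ero1l (0.43), which rose, and P4ha2 (-0.71), a collagen-modifying enzyme gene, which fell alongside the stromal markers (median -3.22). The 9 became 5 without XKO 1 and 4 without XKO 2 or XKO 3, the 2 became 1 without XWT 1, XWT 2, XKO 2 or XKO 3 and 4 without XWT 3, and the call of Ero1l ended without XKO 2. The glycolysis and hypoxia list was called higher without XWT 2 (camera adjusted p = 0.0340), with the stricter filter (0.0486), DESeq2 (0.0395), limma-voom (0.0362), quality weights (0.0335) and length and GC trends removed (0.0143, median 0.19). Genes of lipid uptake, storage and efflux were higher in 2 and lower in 4 of 35 tested members (5 and 4 adjusted over the list alone; median 0.02; camera adjusted p = 0.472). Apoe fell from 4255 ± 784 to 2736 ± 150 CPM (SD, n = 3 each), Pdk4 fell by 2.59 and Angptl4 by 0.44 on the log2 scale, and Scd2 rose by 0.33. The 2 became 1 without XWT 2 or any XKO library, 4 without XWT 1 and 6 without XWT 3.

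Nuclear-encoded genes of oxidative phosphorylation were lower in 3 and higher in 0 of 47 tested members (0 and 0 adjusted over the list alone; median -0.10). Among them were Cox4i1 (-0.24) and Ndufa13 (-0.27), with edgeR adjusted p-values of 0.0441 and 0.0492. Camera called the list (adjusted p = 0.0202; adjusted p = 0.715 with an estimated correlation), but not without XWT 2 (median -0.02) or XKO 2 (-0.08) nor with library size alone (-0.03). The 3 became 0 without XWT 2 or any XKO library, and 13 without XWT 3, and neither Cox4i1 nor Ndufa13 was called without any library but XWT 3, with library size alone or with length and GC trends removed. Ndufa13 was also not called with the stricter filter or limma-voom. The 14 tested mitochondrially encoded genes included 0 called genes (0 and 0 adjusted over the list alone; median 0.13; camera adjusted p = 0.594), with mt-Co2 at -0.24 and mt-Nd6 at 0.22. Of the list, 3 were higher without XWT 1, where the list was called (median 0.26), and 1 was lower without XWT 3. With length and GC trends removed the list median was -0.23, and the list and mt-Co2 were called lower. With upper-quartile factors mt-Co2 was called lower, and with no filter mt-Nd6 was called higher. Of 28 tested genes of mitophagy and autophagy, 1 was higher and 5 lower (2 and 5 adjusted over the list alone; median -0.03; camera adjusted p = 0.312). The cargo receptor gene Sqstm1 rose from 1030 ± 28.4 to 1528 ± 7.59 CPM (SD, n = 3 each), and the kinase genes Ulk1 and Ulk2 fell by 0.35 and 0.31 and Calcoco1 by 0.26 on the log2 scale. The 1 became 2 without XWT 1 or XWT 3, the 5 became 2 without XWT 2, XKO 1 or XKO 3, 1 without XKO 2 and 8 without XWT 3. The call of Ulk2 ended without XKO 2, and that of Calcoco1 without XWT 2 or any XKO library and with library size alone. With length and GC trends removed Ulk1 and Calcoco1 were not called.

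Cell cycle genes were lower in 8 and higher in 0 of 40 tested members (0 and 9 adjusted over the list alone; median -0.12, and -0.05 with library size alone). The falls included the cell cycle inhibitor gene Cdkn1a (-0.49), which acts against proliferation, as well as Ccnd1 (-0.38), Ccnb2 (-0.47) and Cdc20 (-0.50), which act for it. By camera the list was called (adjusted p = 0.0139; adjusted p = 0.708 with an estimated correlation), but not without XKO 3, where the median was -0.06. Between the same groups the stromal markers fell (median -3.22), and a link to the cell cycle genes was not tested. The 8 became 4 without XWT 1, XKO 1 or XKO 2, 2 without XWT 2 and 1 without XKO 3, and 2 genes were higher without XWT 3. The calls of Ccnd1, Ccnb2 and Cdc20 ended without XKO 3, those of Ccnb2 and Cdc20 without XWT 2, and that of Ccnb2 without XKO 2.

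Of 30 hepatocyte markers 1 was tested, Apoa2 at 0.51 ± 0.19 CPM in XWT and 0.30 ± 0.017 CPM in XKO (SD, n = 3 each; edgeR adjusted p = 0.249). Dendritic cell markers had 0 higher and 1 lower of 9 tested (0 and 1 adjusted over the list alone; median -0.01; camera adjusted p = 0.594), the actin-bundling gene Fscn1 (-1.82), and 1 higher and 2 lower without XWT 3. Endothelial and sinusoidal markers had 0 higher and 3 lower of 7 tested (1 and 3 adjusted over the list alone; median 0.09 and mean -0.13; camera direction lower, adjusted p = 0.594): Stab2 (-0.97), Pecam1 (-0.54) and Eng (-0.29). The 3 became 1 without XWT 2 or XKO 1 and 0 without XKO 2; the calls ended for Pecam1 without XKO 2, for Stab2 without XWT 2, XKO 1 or XKO 2, and for Eng without each library but XWT 3, with library size alone and with length and GC trends removed. Of 4 tested lymphocyte and NK cell markers, Ighm (-1.27) and Cd4 (-0.92) fell and Il7r (0.52) rose (1 and 3 adjusted over the list alone). Of 3 tested mast cell and basophil markers 0 were called, with Kit at 0.84 and Hdc at -0.44, and of 3 erythroid and megakaryocyte markers 0 were called, with Pf4 at 0.07 and Ppbp at 0.27 (0 and 0 adjusted over each list alone). Of 4 tested sex-linked genes the Y-linked Ddx3y rose by 0.48 on the log2 scale (3 and 0 adjusted over the list alone), a call that ended without XWT 2, XKO 2 or XKO 3, and 3 were higher without XWT 3.

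**Figure D3:**
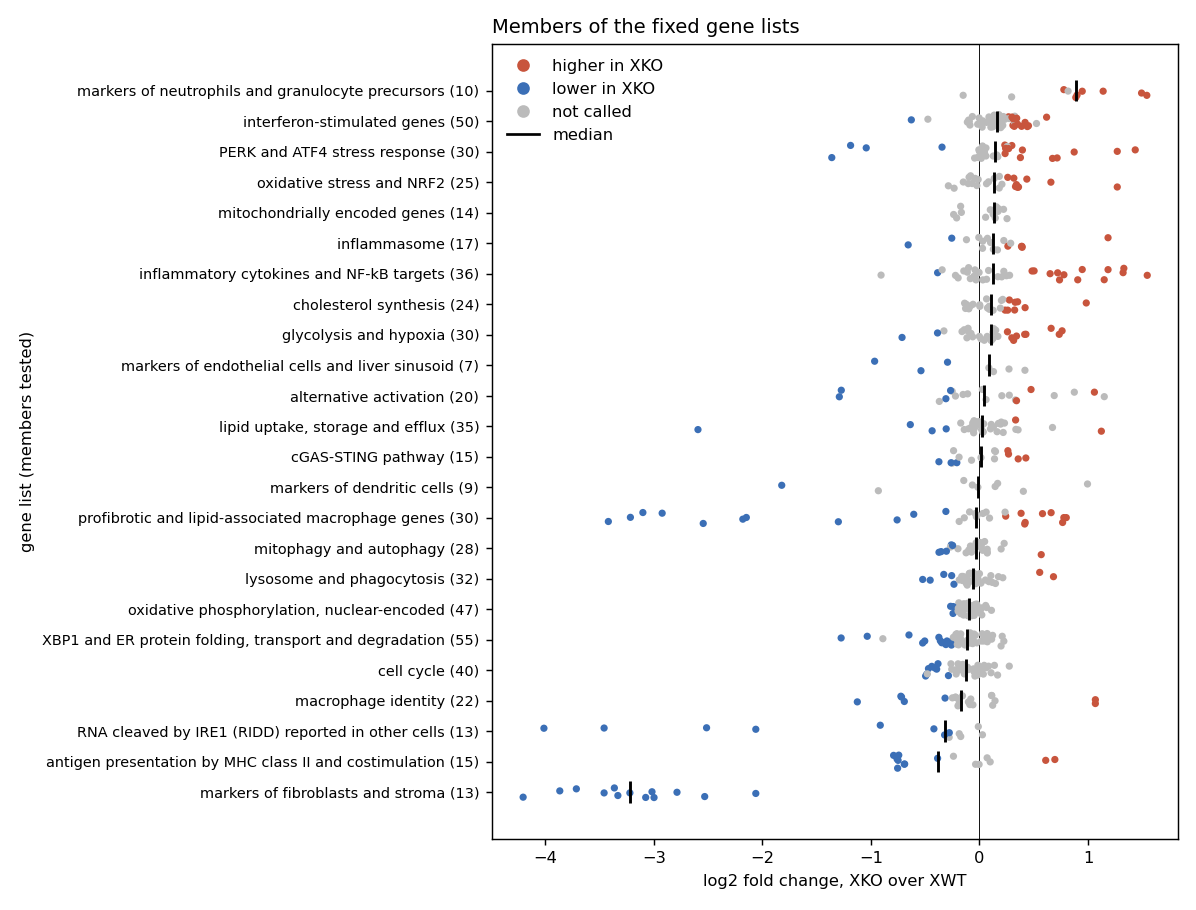
Log2 fold change of XKO over XWT (horizontal axis) for each tested member (points) of the 24 tested gene lists, ordered by list median (black line), with the number of tested members in brackets and colour for higher, lower or not called at an edgeR adjusted p under 0.05. Stromal markers, at a median of -3.22, and neutrophil markers, at 0.89, stand at the ends of the scale, while the other medians lie between -0.39 and 0.17.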

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

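Quality weights per library, removal of length and GC trends, the count without genes over 4-fold lower and the use of the authors' deposited table were chosen after seeing the data. Xbp1 was called in every setting run, with log2 fold changes from -0.87 (library size alone) to -1.02 (without XWT 3). The 2005 changed genes became 2022 with RLE factors, 2047 with upper-quartile factors, 1907 with library size alone, 2834 with no filter, 1612 with the stricter filter, 2111 with DESeq2, 2077 with limma-voom, 2102 with established symbols alone, 2500 with quality weights, 2476 with length and GC trends removed and 1755 without genes over 4-fold lower. None of the 2005 was called in the opposite direction in any of the refits. Leaving out 1 library gave 806 to 4237 genes. A 2-fold minimum gave 481 genes, an adjusted p under 0.01 gave 806 and under 0.1 gave 3164, by construction of the threshold. Of 24 tested lists, 13 were called by camera, 12 to 14 when 1 library was left out, 0 with an estimated correlation, 14 by fry for direction and 22 by fry for change either way, which compares no list with other genes. By fry for direction the macrophage identity, cell cycle, NRF2 and oxidative phosphorylation lists were not called, and the inflammasome, glycolysis, profibrotic, dendritic and endothelial lists were. The median of the mitochondrially encoded genes went from 0.13 to -0.23 with length and GC trends removed (camera adjusted p = 0.00167); the cause was not tested. Over the other settings its adjusted p lay between 0.0465 (without XWT 1) and 0.966 (without XWT 3). Of 1786 recomputed values of 112 named genes, 1707 kept their direction and side of the threshold, 76 lost the call, 3 gained one and 0 reversed; of 479 for lists, 420 kept both, 30 lost the call, 28 gained one and 1 reversed.

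The replicate numbers did not pair the libraries: deviations from the group means of same-numbered libraries correlated at -0.20, -0.05 and -0.02 over genes, and 0 of 3 XWT libraries correlated best with their own number. A replicate block gave 2195 genes (1068 higher, 1127 lower), 12 lists, and -0.94 for Xbp1; the macrophage identity list (camera adjusted p = 0.0575) and Trim32 (edgeR adjusted p = 0.0661) were not called under it.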

Other observations

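In this part, the tests of scaling, of the count of transcription factors, of the size of the Lyz2 change, of reads shared with Lyz1 and of mixing in XWT 3 were chosen after their results were seen, and so were the genes named next. Several genes outside the lists were lower in XKO. Cd5l, a scavenger-type protein gene of tissue macrophages, fell from 111 ± 14.4 to 37.8 ± 2.17 CPM (log2 fold change -1.56 ± 0.090, SE; edgeR adjusted p = 5.91e-08). Fcrls (-0.99), the growth factor gene Gdf3 (-1.04), the ligand gene Gas6 of the TAM receptors (-0.90) and the selenium transport gene Selenop (-0.73) fell too. The stromal markers fell between the same groups (median -3.22), and which cells expressed these genes was not tested. Higher in XKO were Clec4e, the receptor Mincle, from 248 ± 35.7 to 493 ± 14.6 CPM (0.99 ± 0.090, SE; edgeR adjusted p = 6.26e-06), the prostacyclin receptor gene Ptgir (1.04), the receptor gene Met of hepatocyte growth factor (1.04) and the protease inhibitor gene Slpi (1.03). The spreads are SD with n = 3 per group.

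For the 13 stromal markers, far lower in XKO (median log2 fold change -3.22), a test set before its result was seen took transcription factors of mesenchymal cells, which are not secreted: the 8 that were tested had a median of -3.38, but a 95% bootstrap interval over genes of -3.81 to -0.03, because 2 of the 8, among them Scx (-0.03), did not pass, so by this median fewer mesenchymal cells and lower matrix expression within macrophages cannot be told apart. Of the 8, 6 were called lower, a count taken after that outcome. Membership in the 8 favours factors high in XWT, since some passed the filter through XWT (Tbx18, 43 counts there and 3 in XKO). Over all 30 factors of the list, tested or not, the counts were 1206 in XWT and 271 in XKO. These values argue against a fall of genes of secreted proteins only. With library size alone, the 14333 tested genes had a median log2 fold change of 0.0695 (quartiles -0.09 to 0.26). Library size sets every library to the same total, which holds this median near 0, so the median cannot decide about scaling. A factor moves every gene alike, so it would leave the gap between the stromal markers and the other genes unchanged. A test of liver stellate cells as the source of such cells did not decide. In XWT, 3 of 12 stellate markers stood at 1 CPM or more, and 1 of 17 limb patterning genes, Shox2, at 0.5 CPM or more. Of those 3, Nes fell (-1.64) while Hgf (0.07) and Ecm1 (-0.05) were not called. Lrat had 0 and Des 16 counts over the XWT libraries. The limb patterning genes Pitx1 (-2.59) and Shox2 (-2.15) were called lower in XKO, and the others were too low to test. Both groups had medium of wild-type hepatocytes, so cells carried with it would not by themselves account for a gap between the groups. The source of any such cells stays open.

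Lyz2 fell to under 50% of its XWT level. A candidate explanation is loss of 1 Lyz2 allele to an inserted Cre gene, which the labels do not name; its log2 fold change of -1.13 (95% interval -1.31 to -0.94) includes the -1 this would give. The gain of Lyz1 was 0.0555% of the loss of Lyz2 in CPM, which argues against reads moved to the paralog. The other macrophage identity genes had a median of -0.16 (95% bootstrap interval -0.22 to -0.06), which argues against a general fall of these genes as the whole cause. DNA of another strain around Lyz2 stays open: 16.5% of 79 tested genes within 10 Mb were called, against 1990 of 14252 others (Fisher's exact test, two-sided, p = 0.515).

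XWT 3 lay nearer to the XKO libraries than XWT 1 and XWT 2 did. Its median position between the groups was 0.56 over 1387 genes, where 0 is the mean of XWT 1 and XWT 2 and 1 that of XKO (0.67 for genes higher in XKO, 0.31 for genes lower). These genes were picked from those called in the fit without XWT 3, with the stromal markers left out. Picking on the values of XWT 1 and XWT 2 can by itself move XWT 3 towards XKO, so 0.56 may be too high. Mixed-in XKO material at a share of 0.56 would leave the stromal markers at 0.504 of their level, and a smaller share would leave more. They stood at 1.15 (95% bootstrap interval 1.02 to 1.19), which argues against a mixture of that size. The interval covers the spread between markers in 1 library, not between cultures. A mixture offset by more stromal transcripts in XWT 3 itself therefore cannot be excluded. By another measure, the projection of XWT 3 on the log2 difference between the groups over 9143 genes, it stood at 0.37 and after removal of length and GC trends at 0.33, 90.3% of that value, which argues against those trends as the whole cause. No biological explanation was tested, and a difference between cultures or animals stays open.

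The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2005 genes and was the 1 split with as many. The highest other split gave 0, with 59 to 687 genes at an unadjusted p under 0.05 in edgeR, against 4409 for the real split. Every other split has XWT and XKO libraries on both sides, so the group difference adds to its residual spread. Few calls there follow by construction, and the splits cannot decide about chance.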
